A study of Mus musculus with 10 samples.

How the data were processed

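Bulk RNA sequencing of 10 subcutaneous RENCA tumours was analysed from the values deposited by the authors, 5 from mice injected with PBS and 5 from mice injected with SLR14 in 50 µL of PBS. Per the labels' protocols, total RNA was extracted from the tumours, ribosomal RNA was depleted, messenger RNA was enriched with oligo(dT) beads and fragmented, and cDNA was made with random primers. Ribosomal depletion and oligo(dT) enrichment together measure polyadenylated RNA. Per the submitters' processing notes, Trim Galore 0.6.7, STAR, DESeq2 1.36.0 and the mm39 genome build were used. The counting program, its strand setting and the gene annotation are not given in the sources used here, so reads from overlapping and antisense genes could not be told apart and counts of near-identical paralogs are uncertain.

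The first deposited table holds raw counts per gene, whole numbers with 1 column per tumour and 18603 genes. In the values, each gene has a normalized value of at least 5 in at least 3 samples. The second deposited table holds a normalized signal, the counts divided by 1 factor per sample. These factors lie close to the median-of-ratios size factors of the raw counts, as DESeq2 makes them. The count table was used for all main tests, and the normalized values for 1 alternative. No gene symbol was given for 74 genes, which held 0.0295% of the counts. They were kept, since each has a gene identifier in the deposited counts. Of the identifiers, 17797 matched the reference annotation at hand (GENCODE M21 on GRCm38), which is not the build named by the submitters, so no coordinates are given and gene symbols are those of the deposited tables.

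Groups were taken from the sample titles, and the design text states 5 mice in each group. Pairs of tumours within a group differed by more than counting noise (chi-square per degree of freedom 8.15 to 146 over 20 pairs, Pearson r across genes 0.969 to 0.992, where genes are not independent replicates), so no library was counted as a duplicate. Total counts per tumour ranged from 17931895 to 39842608. Mitochondrial genes took 0.495 ± 0.183% of counts in PBS and 0.594 ± 0.146% in SLR14 tumours (SD, n = 5, exact permutation p = 0.389).

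Genes were filtered with filterByExpr by group (minimum count 10), which kept 15883, and normalized with TMM. The main test was edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest) of SLR14 against PBS in R 4.3.3, over all 10 samples, with no covariate and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was derived from it as its absolute value divided by the square root of F. The common biological coefficient of variation was 0.190. CPM values are scaled by TMM. Fold changes come from edgeR's model, whose prior count shrinks those of low genes.

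Gene lists for interferon responses, antigen presentation, immune and vascular cell types, cell death, metabolism and neighbouring tissues were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. A list with at least 5 tested genes entered camera, fry and the list scores, which gave 34 lists, and 7 smaller ones are described gene by gene. Camera of limma 3.58.1 was run on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation, and fry beside it. A list score is the mean log2(CPM + 1) of the tested genes of a list, compared by a two-sided exact permutation test over 252 assignments, whose smallest p is 0.00794. Relative scores subtract the score of 1 list from that of another for 10 pairs and had no minimum size, so that 3 of the smaller lists entered them, cytotoxic effectors and regulatory T cells with 4 genes each and lymphatic endothelium with 3. Adjustment was over the 34 lists or 10 pairs. Lists share some genes, such as Bst2 and Zbp1, which are also on the interferon-stimulated list.

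The named genes are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean CPM of at least 1 and no overlap between groups. Predicted genes, pseudogenes, receptor segments and rows with no symbol were left out of that choice. To these were added the 3 genes with the smallest p of each list, the member with the smallest p in the minority direction where a list passed in both directions, and a fixed set including Rigi, Ifih1, Mavs, Isg15, Cxcl9, Cxcl10, Cd8a, Gzmb, Cd274, Pdcd1, Pecam1, Vegfa, Col1a1 and Mki67. The rule gave 139 genes. Ifnb1 and Ifng belong to the fixed set and were not analysed here. Genes outside the rule are said to be named after their values were seen, and those called were refitted without each tumour too. The value of 1 of the named genes is not reported here, though counts of genes and of values include it.

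Alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0 with its own filter in place of filterByExpr, limma voom with and without sample quality weights, limma on the authors' normalized values, other low-count filters, a replicate block, library size as a covariate, other pseudocounts and score definitions, and leaving out each tumour in turn. Leaving out PBS 5 and SLR14 2 together, scores without Zbp1, Nt5e or Bst2, and DESeq2 on the genes edgeR tested were added after the data were seen. The test was checked on simulated counts of 15689 genes for the SLR14 against PBS comparison. It recovered 82 of 100 genes changed by 1 and 95 of 99 changed by 2 on the log2 scale, and called 8 of 15490 unchanged genes. In the simulated lists the 1 shifted list was called, and 1 of the unshifted lists was called too. Simulated genes were drawn independently of each other, so this does not show how often camera calls lists of correlated genes by chance.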

Results

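RNA was sequenced from tumours of RENCA, a mouse kidney cancer cell line that grows in Balb/c mice, implanted under the skin of female animals. The treated tumours were injected with SLR14, a stem-loop RNA with a triphosphate end that binds RIG-I, the cytosolic sensor of viral RNA, packed in lipid nanoparticles. The control tumours were injected with PBS, the vehicle, so the contrast holds the RNA and its lipid carrier together. Mice were randomized when tumours measured 100 to 150 mm3, received 3 injections 48 h apart, and gave up their tumours 24 h after the last one. Each group held 5 tumours from 5 mice. The question posed by the design is how gene expression in the whole tumour, which mixes cancer, immune, vascular and connective tissue cells, differed after the RIG-I agonist. PBS tumours 1 to 5 had total counts of 28509930, 31865910, 25138637, 34024137 and 24161644. SLR14 tumours 1 to 5 had 24301254, 17931895, 39842608, 20048831 and 37908548, and the groups' mean depth did not differ by a two-sided exact permutation test (p = 0.881).

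After SLR14, 29 of 40 interferon-stimulated genes, 4 of 19 class I antigen presentation genes and 5 of 13 neutrophil genes were higher, and a small set of genes including Cd209a, Ear2, Mucl1 and Asgr2 was lower. Camera called these 3 lists higher with its preset correlation and none of them with an estimated one (adjusted p = 0.0812, 0.161 and 0.161). Irf7, the transcription factor that amplifies type I interferon, went from 37.0 ± 6.45 to 204 ± 77.7 CPM (library-scaled counts; SD, n = 5), and Slfn4, a Schlafen gene of myeloid cells, from 2.79 ± 1.43 to 23.8 ± 10.3 CPM. In the opposite direction Asgr2, a subunit of the asialoglycoprotein receptor, went from 12.3 ± 1.98 to 1.05 ± 0.412 CPM. Of 15883 genes tested with edgeR's quasi-likelihood test, 153 passed a Benjamini-Hochberg adjusted p of 0.05, 107 of them higher and 46 lower in SLR14 tumours. Among these, 70 higher and 35 lower genes had an absolute log2 fold change over 1. At an unadjusted p under 0.05 there were 1721 genes, where chance gives 794. DESeq2, which tested 18584 genes, called 407, 251 higher and 156 lower, among them each of the 153. The edgeR count was 69 without PBS 1, 78 without PBS 3, 77 without SLR14 1, 75 without SLR14 3 and 89 without SLR14 4. Higher genes numbered 70 without PBS 2 and lower genes 71 without PBS 5, and no shared call changed sign.

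**Figure D1:**
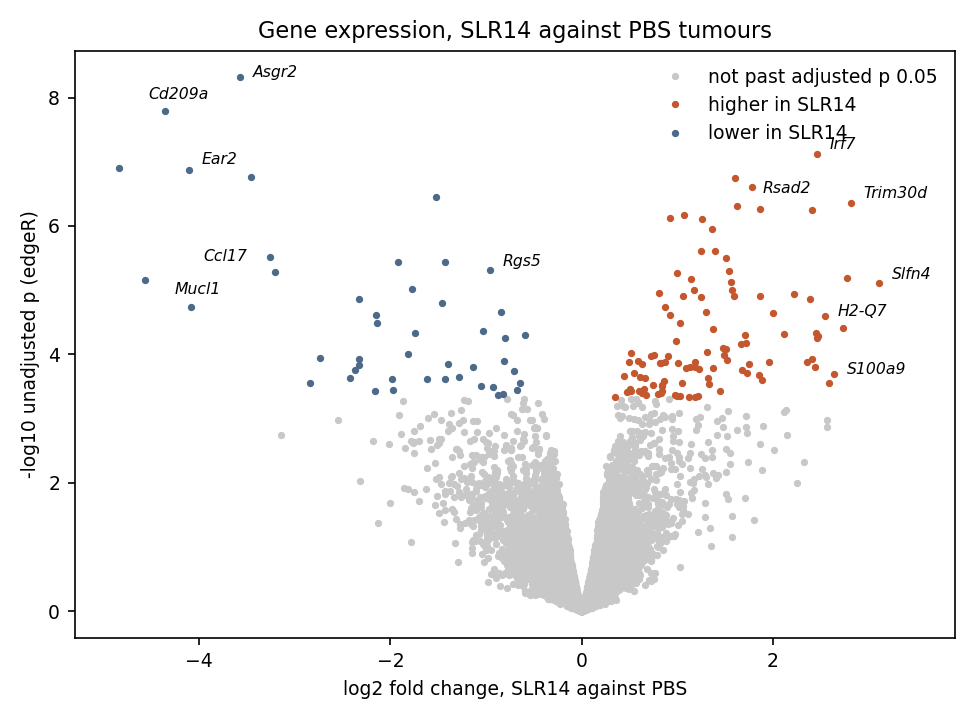
Each point is 1 of the 15883 genes tested, with the log2 fold change of SLR14 against PBS tumours on the x axis and -log10 of the unadjusted edgeR p on the y axis. The 107 orange genes were higher and the 46 blue genes lower at an adjusted p of 0.05, and Cd209a lies at -4.36.

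The first principal component of log2 CPM held 28.3% of the variance and separated the groups, with a mean of 17.2 in PBS and -17.2 in SLR14 tumours (exact permutation p = 0.00794, the smallest that 252 assignments can give, unadjusted for the 4 components tested). PBS 5 at 58.1 and SLR14 2 at -42.1 stood apart from the rest. Without both, 215 genes passed, 141 higher and 74 lower, an alternative added after the data were seen. PBS 5 had the highest erythroid score of the PBS tumours (3.83, others 2.69 to 2.77), and SLR14 2 had the lowest skeletal muscle score (0.310, other SLR14 tumours 2.51 to 3.51).

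Interferon-stimulated genes gave the broadest change. Of the 40 genes on this list, 29 rose, 0 fell and 11 did not pass, and 36 rose when adjusted over the list alone. The fold change was positive for all 40, with a median log2 fold change of 1.00. Irf7 (ENSMUSG00000025498) rose by 2.46 on the log2 scale (SE 0.23, edgeR adjusted p = 0.000396). Rsad2, the antiviral protein viperin, rose by 1.78 (SE 0.19, edgeR adjusted p = 0.000493) and Oasl2, an oligoadenylate synthetase-like protein, by 1.62 (SE 0.18, edgeR adjusted p = 0.000687). Isg15, an interferon-induced ubiquitin-like modifier, had a log2 fold change of 0.81 (SE 0.21) and did not pass (edgeR adjusted p = 0.122). It gained the call in 3 of 15 alternatives, and PBS 5 had 69.3 CPM against 32.3 to 41.3 in the other PBS tumours. The list score, the mean log2(CPM + 1) of its genes, was 4.18 ± 0.108 in PBS and 5.12 ± 0.267 in SLR14 tumours (SD, n = 5), higher in all 5 SLR14 tumours than in any PBS tumour (exact permutation p = 0.00794, adjusted 0.045). The score did not pass without any 1 tumour other than SLR14 4 (adjusted exact permutation p 0.0540 to 0.0694) or with a median over genes (adjusted 0.225). In each of these fits its unadjusted exact permutation p stayed at 0.00794, the smallest possible, so the loss came with the adjustment over lists. The difference was 0.932 in the main test and 1.05 with a median over genes. In the camera test, which compares a list with all other genes, the adjusted p was 2.47e-52 with the preset correlation. With an estimated correlation the adjusted p was 0.0812, and fry, which asks whether the genes move one way, gave 0.00282.

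Beyond that list, the largest rises included Slfn4 (log2 fold change 3.11, SE 0.44, edgeR adjusted p = 0.00382), Trim30d (2.81, SE 0.31, edgeR adjusted p = 0.000687), Slfn1 (2.41, SE 0.27, edgeR adjusted p = 0.000687) and Ms4a4c (2.39, SE 0.36, edgeR adjusted p = 0.00515). Schlafen, Trim30, Ifit, Oas and class I genes of the H2-Q region belong to families with similar copies, and values of single members are uncertain to the extent that reads were shared between copies.

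The target of the agonist and its relative were among the genes that rose. Rigi (ENSMUSG00000040296), the RIG-I gene, went from 26.9 ± 6.89 to 47.7 ± 2.81 CPM (SD, n = 5; log2 fold change 0.83, SE 0.16, edgeR adjusted p = 0.0241). Ifih1, which encodes the sensor MDA-5, went from 30.7 ± 2.76 to 44.0 ± 6.21 CPM (log2 fold change 0.52, SE 0.11, edgeR adjusted p = 0.0425). Mavs, the adaptor of both sensors, was at 74.7 ± 15.2 and 79.6 ± 5.16 CPM (edgeR adjusted p = 0.794). Of the 18 genes of RIG-I-like receptor sensing and signalling, 2 rose, 0 fell and 16 did not pass, and 3 rose and 1 fell when adjusted over the list alone. The score was 5.65 ± 0.113 in PBS and 5.79 ± 0.0154 in SLR14 tumours (exact permutation p = 0.00794, adjusted 0.045), and PBS 5 had the lowest score, 5.45. Without PBS 5 the score difference went from 0.137 to 0.0813 (adjusted p = 0.0540 in the exact permutation test). The score did not pass without any 1 of the 10 tumours (up to 0.135) or with a median over genes (adjusted exact permutation p 0.306). Camera gave an adjusted p of 0.0409, or adjusted p = 0.313 with an estimated correlation, and did not call the list without PBS 1, 3, 4 or 5 or SLR14 1 or 3 (adjusted p 0.0520 to 0.0638). Rigi lost its call in edgeR without PBS 1, 2 or 3 or SLR14 1, 3, 4 or 5 (adjusted p 0.0577 to 0.0753), and Ifih1 without any 1 tumour other than PBS 5 or SLR14 2 (0.0538 to 0.140). Of the 5 tested interferon ligand and receptor genes 0 passed in edgeR, DESeq2 or limma voom, 2 had an unadjusted p under 0.05, and 1 rose and 1 fell when adjusted over the list alone. Ifnb1 and Ifng were not analysed here.

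Genes of class I antigen presentation rose, in part. Of 19 tested, 4 rose, 0 fell and 15 did not pass, 16 rose when adjusted over the list alone, and all 19 had positive fold changes with a median of 0.57. H2-Q7, a non-classical class I gene, went from 0.776 ± 0.512 to 4.59 ± 1.63 CPM (SD, n = 5; log2 fold change 2.54, SE 0.40, edgeR adjusted p = 0.00763). H2-Q6 rose by 1.67 (SE 0.29, edgeR adjusted p = 0.0160) and H2-Q4 by 0.72 (SE 0.13, edgeR adjusted p = 0.0219) on the log2 scale. The other call was Tap1, the peptide transporter, named after its values were seen (0.82, SE 0.18, edgeR adjusted p = 0.0451). The list score was 6.54 ± 0.188 in PBS and 7.13 ± 0.185 in SLR14 tumours, higher in all 5 SLR14 tumours (exact permutation p = 0.00794, adjusted 0.045). It did not pass without any 1 tumour other than SLR14 4 (adjusted exact permutation p 0.0540 to 0.111), and the exact permutation p was 0.0159 without SLR14 1, 3 or 5. With a median over genes it did not pass either (exact permutation p = 0.0397, adjusted 0.225). The camera adjusted p was 9.32e-18, with adjusted p = 0.161 with an estimated correlation and 0.0205 in fry. H2-Q6 lost its call without PBS 1, PBS 3 or SLR14 1 (edgeR adjusted p 0.0530 to 0.0604), and H2-Q4 without PBS 1, 2 or 3 or SLR14 1, 3 or 5 (0.0529 to 0.0732). Tap1 lost its call without any 1 tumour other than PBS 4 (0.0540 to 0.139).

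Genes responding to interferon gamma showed 5 of 20 rising, 0 falling and 15 not passing. Adjusted over the list alone, 13 rose and 1 fell. Gbp3, an interferon-induced GTPase, rose by 1.38 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0258), Serping1, the complement C1 inhibitor, by 1.19 (SE 0.23, edgeR adjusted p = 0.0256) and Gbp2 by 1.05 (SE 0.22, edgeR adjusted p = 0.0361). The others were Irgm1 (0.84, edgeR adjusted p = 0.0376) and Gbp9 (1.00, edgeR adjusted p = 0.0475), named after their values were seen. Gbp3 lost its call without PBS 1 or 3 or SLR14 1, 3 or 5 (edgeR adjusted p 0.0675 to 0.0842), Serping1 without PBS 1 or 3 or SLR14 1, 4 or 5 (0.0582 to 0.0796), and Gbp2 without any 1 tumour other than PBS 2, PBS 4 or SLR14 2 (0.0538 to 0.114). Irgm1 and Gbp9 lost theirs without any 1 tumour other than PBS 2 or SLR14 2 (0.0519 to 0.125 and 0.0643 to 0.151). Camera gave an adjusted p of 1.38e-10, or adjusted p = 0.313 with an estimated correlation, and the score did not pass (exact permutation p = 0.0317, adjusted 0.154).

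Class II antigen presentation genes did not share this direction. Of 8 tested, 0 passed in edgeR, 1 had an unadjusted p under 0.05 and 1 passed in DESeq2, while 7 had negative fold changes with a median of -0.70. Adjusted over the list alone, 1 fell. H2-Eb1 was at 120 ± 44.7 CPM in PBS and 56.8 ± 52.6 CPM in SLR14 tumours (edgeR adjusted p = 0.487). Scores of 5.29 ± 0.326 and 4.50 ± 0.848 overlapped (exact permutation p = 0.0952), and PBS 4 had the highest PBS score, 5.84. Camera called the list lower (adjusted p = 0.000342), with adjusted p = 0.479 with an estimated correlation and 0.265 in fry.

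**Figure D2:**
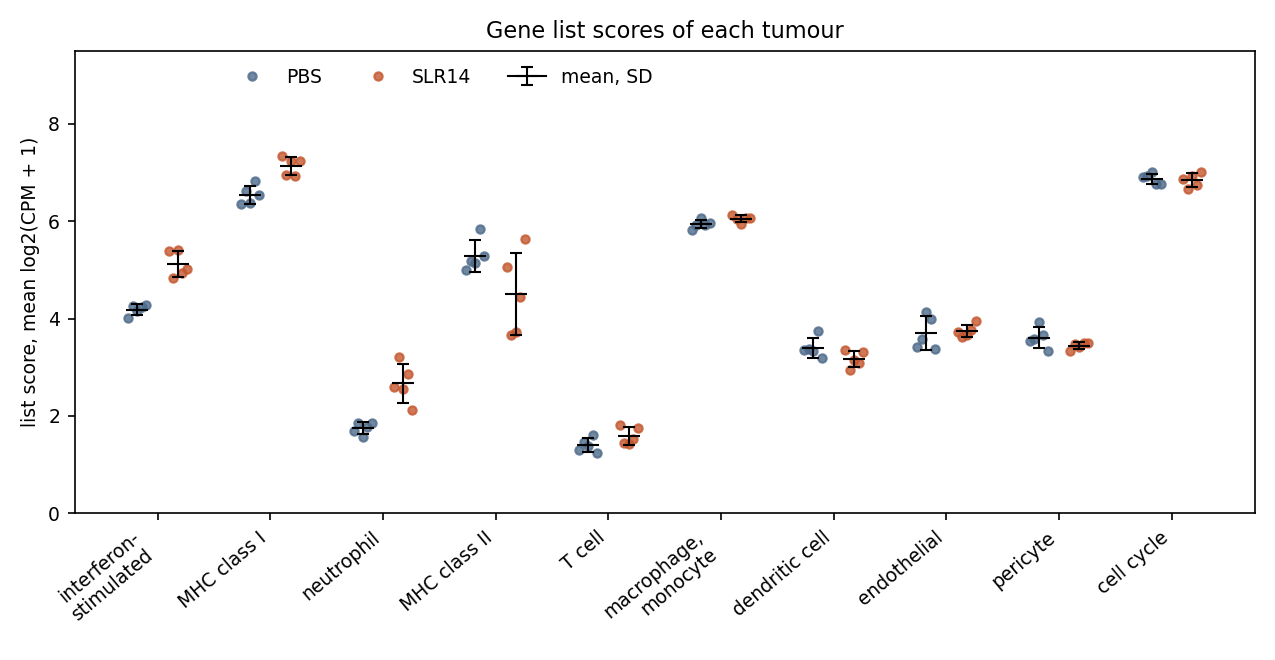
Each point is 1 tumour, with the mean log2(CPM + 1) of a gene list on the y axis and the list on the x axis, PBS in blue and SLR14 in orange; black bars give the mean and SD of 5 tumours. The groups do not overlap for interferon-stimulated, MHC class I and neutrophil genes, and they overlap for the other 7 lists drawn.

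Chemokine genes moved both ways. Of 22 tested, 3 rose, 1 fell and 18 did not pass, with 9 rising and 2 falling when adjusted over the list alone. Cxcl10 and Cxcl11, ligands of the receptor Cxcr3, went from 1.46 ± 0.459 to 6.74 ± 2.82 CPM (SD, n = 5; log2 fold change 2.22, SE 0.33, edgeR adjusted p = 0.00492) and from 0.193 ± 0.0688 to 1.08 ± 0.556 CPM (2.47, SE 0.42, edgeR adjusted p = 0.0133). The other rise was Ccl7, a monocyte chemokine named after its values were seen (1.14, SE 0.22, edgeR adjusted p = 0.0256). Ccl17, a chemokine of the Ccr4 receptor made by dendritic cells, went from 4.65 ± 2.04 to 0.516 ± 0.282 CPM (log2 fold change -3.26, SE 0.42, edgeR adjusted p = 0.00237). Cxcl9, the other ligand of Cxcr3, was at 2.25 ± 2.06 and 6.51 ± 4.31 CPM and did not pass (edgeR adjusted p = 0.337). Camera gave an adjusted p of 0.000342, or adjusted p = 0.313 with an estimated correlation, and the score did not pass (exact permutation p = 0.0397, adjusted 0.169). Cxcl11 lost its call without PBS 1 (edgeR adjusted p = 0.0534), and Ccl7 without PBS 1, 3 or 4 or SLR14 1 or 3 (0.0542 to 0.0838).

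Cytotoxic lymphocyte genes were measured at low levels. Gzma and Gzmb, the granzymes of killer cells, rose by 2.35 (SE 0.44) and 2.59 (SE 0.53) on the log2 scale from 0.257 ± 0.0941 and 0.193 ± 0.159 CPM in PBS tumours (SD, n = 5; edgeR adjusted p = 0.0241 and 0.0361). Prf1, perforin, was at 0.172 ± 0.125 and 0.778 ± 0.234 CPM (edgeR adjusted p = 0.0657). Of 14 effector genes listed, 7 were in the count table and 4 were tested. Of the 4 tested 2 rose, and 4 rose when adjusted over the list alone. DESeq2 called 4 and limma voom 0 of these 4 genes. Low genes could pass the low-count filter through the SLR14 tumours alone, as Prf1 did (at most 0.339 CPM in PBS, at least 0.453 CPM in SLR14 tumours). The share of tested effector genes that rose is therefore set in part by the filter. Gzma lost its edgeR call without PBS 1, 3 or 4 or SLR14 1, 3 or 4 (adjusted p 0.0535 to 0.0759), and Gzmb without any 1 tumour other than PBS 2, SLR14 4 or SLR14 5 (0.0626 to 0.108).

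T cell genes did not pass singly. Of 12 tested, 0 passed in edgeR, 5 had an unadjusted p under 0.05, 3 passed in DESeq2 and 1 in limma voom, and 3 rose when adjusted over the list alone. Cd3e was at 0.183 ± 0.226 CPM in PBS and 1.15 ± 0.531 CPM in SLR14 tumours (edgeR adjusted p = 0.0791), and Cd8a at 0.240 ± 0.203 and 1.10 ± 0.715 CPM (edgeR adjusted p = 0.111). Camera called the list higher (adjusted p = 0.0394), with adjusted p = 0.496 with an estimated correlation and 0.160 without SLR14 5. A filter of 1 CPM in 5 samples removed members such as Cd3e and Cd8a, and camera's direction for those left turned (median -0.04, adjusted p = 0.750). The membership of the list changed, so this does not show T cell genes changing direction. The score of the 12 genes did not pass (exact permutation p = 0.111). None of the 4 natural killer cell, 4 regulatory T cell, 8 checkpoint and 5 B cell and plasma cell genes passed in edgeR, DESeq2 or limma voom. At an unadjusted p under 0.05 there were 2, 0, 2 and 0 of them. Adjusted over the list alone, 2 natural killer cell genes rose and 0 genes of the other 3 lists passed. Pdcd1, the checkpoint receptor PD-1, was at 0.374 ± 0.209 and 0.923 ± 0.588 CPM (edgeR adjusted p = 0.351), and Cd274, its ligand PD-L1, at 29.6 ± 9.19 and 24.6 ± 2.57 CPM (edgeR adjusted p = 0.589). Among 17 inflammatory cytokine and NF-kB genes 0 passed in edgeR, DESeq2 or limma voom and 1 had an unadjusted p under 0.05. The scores of the checkpoint, B cell and cytokine lists did not pass (exact permutation p = 0.413, 0.690 and 0.286).

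Neutrophil genes rose, in part. Of 13 tested, 5 rose, 0 fell and 8 did not pass, and 10 rose when adjusted over the list alone. Lcn2, an iron-trapping protein of neutrophils and of stressed epithelium, went from 36.0 ± 2.70 to 92.7 ± 24.7 CPM (ENSMUSG00000026822; SD, n = 5; edgeR adjusted p = 0.00106). S100a8, a part of the calprotectin complex, went from 0.735 ± 0.217 to 3.25 ± 1.58 CPM (2.11, SE 0.36, edgeR adjusted p = 0.0127), and Mmp8, neutrophil collagenase, from 0.444 ± 0.147 to 2.49 ± 1.39 CPM (2.46, SE 0.42, edgeR adjusted p = 0.0138). Acod1, the itaconate-making enzyme that activated macrophages also express, went from 0.690 ± 0.539 to 3.74 ± 1.21 CPM (edgeR adjusted p = 0.0238), and the other call was S100a9, named after its values were seen (2.64, SE 0.52, edgeR adjusted p = 0.0295). The list score was 1.75 ± 0.119 in PBS and 2.67 ± 0.397 in SLR14 tumours, higher in all 5 (exact permutation p = 0.00794, adjusted 0.045). It did not pass without any 1 tumour other than SLR14 4 (adjusted exact permutation p 0.0556 to 0.0926), and the exact permutation p was 0.0159 without any 1 PBS tumour. With a median over genes it did not pass either (exact permutation p = 0.0238, adjusted 0.225). Camera gave an adjusted p of 2.11e-11, with adjusted p = 0.161 with an estimated correlation and 0.0205 in fry. Limma voom called 2 of the 13 genes and DESeq2 9. Acod1 lost its edgeR call without PBS 1, PBS 4, SLR14 1 or SLR14 3 (adjusted p 0.0507 to 0.0736), Mmp8 without PBS 3 (0.0501), and S100a9 without PBS 1, 2, 3 or 4 or SLR14 1 or 4 (0.0621 to 0.0844). Set against macrophage genes, the neutrophil score went from -4.19 ± 0.173 to -3.38 ± 0.409 (exact permutation p = 0.00794, adjusted over 10 such pairs 0.0794), so the relative score did not pass.

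General macrophage and monocyte genes showed no call in edgeR among 20 tested, with 4 at an unadjusted p under 0.05, 2 calls in DESeq2 and 0 in limma voom, and 1 rising when adjusted over the list alone. Their scores were 5.94 ± 0.0875 and 6.05 ± 0.0686 (exact permutation p = 0.0714). Among 16 genes of alternative macrophage activation, 0 rose, 1 fell and 15 did not pass, and 1 rose and 4 fell when adjusted over the list alone. The gene was Ccl24, an eotaxin, which went from 1.86 ± 0.405 to 0.498 ± 0.0985 CPM (SD, n = 5; log2 fold change -1.92, SE 0.26, edgeR adjusted p = 0.00254). Camera called this list lower (adjusted p = 0.00844, with adjusted p = 0.479 with an estimated correlation), and the score did not pass (exact permutation p = 0.190). None of the mast cell, eosinophil and basophil genes listed was tested.

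Among genes with a mean of at least 1 CPM, the deepest falls were in genes of myeloid and dendritic cells and in genes of other or mixed expression. Cd209a (ENSMUSG00000031494), a C-type lectin of monocyte-derived dendritic cells, went from 2.79 ± 0.783 to 0.135 ± 0.0793 CPM (SD, n = 5; log2 fold change -4.36, SE 0.36, edgeR adjusted p = 0.000129). Ear2, an eosinophil-associated ribonuclease also found in macrophages, had a log2 fold change of -4.10 (SE 0.41, edgeR adjusted p = 0.000406), Asgr2 of -3.57 (SE 0.27, edgeR adjusted p = 7.72e-05) and Alox15, a lipoxygenase, of -3.46 (SE 0.35, edgeR adjusted p = 0.000406). Mucl1, a mucin-like protein, stood at -4.09 (SE 0.63, edgeR adjusted p = 0.00626), Gfra2, a receptor of neurturin, at -3.21 (SE 0.44, edgeR adjusted p = 0.00315), Adam23 at -2.33 (SE 0.35, edgeR adjusted p = 0.00515) and Inmt, a methyltransferase, at -2.15 (SE 0.34, edgeR adjusted p = 0.00756). Cd209a and Ear2 have close paralogs, so counts of single members are uncertain. Of 12 dendritic cell genes, 2 fell (Cd209a and Zbtb46), 1 rose (Bst2) and 9 did not pass, and 3 fell and 1 rose when adjusted over the list alone. Bst2, tetherin, marks plasmacytoid dendritic cells and is also on the interferon-stimulated list (1.39, SE 0.18, edgeR adjusted p = 0.00205). Zbtb46, a transcription factor of conventional dendritic cells, fell by 0.93 on the log2 scale (SE 0.19, edgeR adjusted p = 0.0398) and lost its call without any 1 tumour other than PBS 5 or SLR14 1 (adjusted p 0.0679 to 0.130). Camera did not call the dendritic cell list (adjusted p = 0.106, or 0.528 with an estimated correlation), nor did its score pass (exact permutation p = 0.0556). Camera called it lower without the genes that several lists hold, Bst2 among them (adjusted p = 0.00840), without PBS 3 (0.0266) and without PBS 5 (0.0474), all with the preset correlation, while the score without Bst2, a test added after the data were seen, did not pass (exact permutation p = 0.0238, adjusted 0.116).

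**Figure D3:**
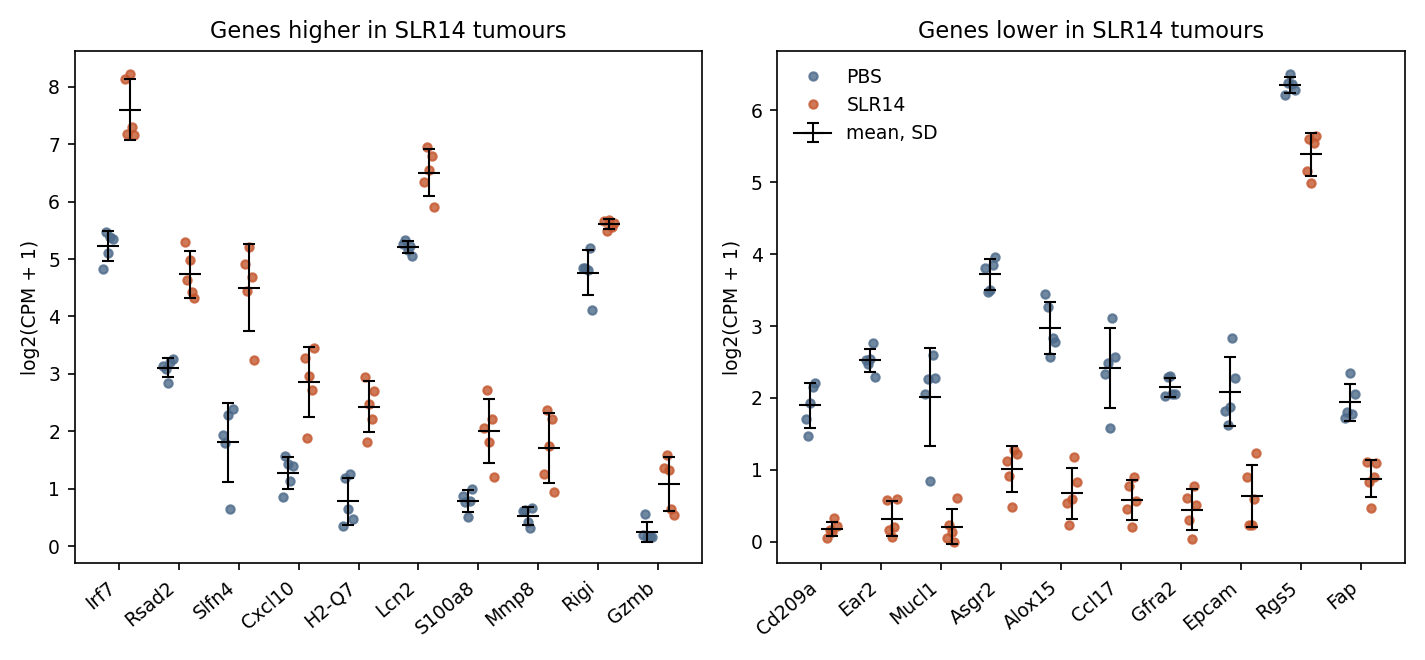
Each point is 1 tumour, with log2(CPM + 1) on the y axis and the gene on the x axis, PBS in blue and SLR14 in orange; black bars give the mean and SD of 5 tumours. The left panel shows 10 genes higher and the right panel 10 genes lower in SLR14 tumours, and the groups overlap only for Gzmb. Most of these genes were named for the largest rise or fall, a choice that required no overlap, so for them its absence was set in advance.

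Vascular genes were compared because the study's title names vascular remodelling. Rgs5, a regulator of G protein signalling in pericytes, the mural cells of small vessels, went from 80.6 ± 6.20 to 41.5 ± 8.24 CPM (SD, n = 5; log2 fold change -0.96, SE 0.13, edgeR adjusted p = 0.00315). It was the 1 call among 15 pericyte and mural cell genes, of which 2 fell and 0 rose when adjusted over the list alone. Camera called this list lower (adjusted p = 0.0394), with adjusted p = 0.464 with an estimated correlation and up to 0.246 in the fits without PBS 3, PBS 4 or SLR14 1. The score of 3.61 ± 0.217 against 3.44 ± 0.0660 did not pass (exact permutation p = 0.143). Of 24 pan-endothelial genes, 0 passed in edgeR, DESeq2 or limma voom and 0 had an unadjusted p under 0.05. Pecam1, the endothelial adhesion molecule CD31, was at 43.2 ± 11.7 and 38.4 ± 7.33 CPM (edgeR adjusted p = 0.735). Of 15 tip cell and angiogenic endothelial genes 0 passed in edgeR, 3 had an unadjusted p under 0.05 and 1 passed in DESeq2, with 1 falling when adjusted over the list alone. Of 15 angiogenic ligands and modulators 0 passed in edgeR or DESeq2 and 3 had an unadjusted p under 0.05, and of 8 endothelial adhesion genes 0 passed in edgeR, DESeq2 or limma voom and 0 had an unadjusted p under 0.05. Adjusted over the list alone, 0 genes of the pan-endothelial, ligand and adhesion lists passed. Vegfa, the main endothelial growth factor, was at 229 ± 59.4 and 261 ± 28.6 CPM (edgeR adjusted p = 0.676). Of 3 lymphatic endothelial genes, 0 passed in edgeR or DESeq2, 1 had an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. The scores of the pan-endothelial, tip cell, ligand and adhesion lists did not pass (exact permutation p = 0.802, 0.952, 0.754 and 0.603). For the first 3 of these the median, mean, camera direction and score difference did not share a sign, with medians of -0.05, -0.06 and 0.13.

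Fibroblast and matrix genes had 1 call among 21 tested. Fap, a protease of activated fibroblasts, went from 2.89 ± 0.736 to 0.863 ± 0.317 CPM (SD, n = 5; log2 fold change -1.74, SE 0.29, edgeR adjusted p = 0.0126), and 1 gene fell when adjusted over the list alone. Col1a1, type I collagen, was at 852 ± 533 and 588 ± 199 CPM (edgeR adjusted p = 0.639). Camera called the list lower (adjusted p = 0.00498), with adjusted p = 0.523 with an estimated correlation and 0.132 without PBS 4, and the score did not pass (exact permutation p = 0.135).

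Cell death genes were compared because the title names immunogenic death. Zbp1, a sensor of Z-form nucleic acid that starts necroptosis and is itself an interferon-stimulated gene, went from 8.34 ± 1.72 to 30.4 ± 9.27 CPM (SD, n = 5; log2 fold change 1.87, SE 0.21, edgeR adjusted p = 0.000687). It was the 1 call among 8 necroptosis genes, also when adjusted over the list alone, and Ripk3, the necroptosis kinase, was at 16.6 ± 3.08 and 20.6 ± 2.30 CPM (edgeR adjusted p = 0.434). The necroptosis score was 5.46 ± 0.0748 and 5.74 ± 0.0576 (exact permutation p = 0.00794, adjusted 0.045), while the median log2 fold change was 0.08 against a mean of 0.29 and camera gave an adjusted p of 0.0501, or 0.313 with an estimated correlation. Without Zbp1 the score difference went from 0.273 to 0.0671 and did not pass (exact permutation p = 0.0476, adjusted 0.202), a test added after the data were seen. Among 14 danger signal genes 1 rose and 13 did not pass, and 4 rose when adjusted over the list alone. The gene was Nt5e, the nucleotidase CD73 that turns AMP into adenosine, which went from 3.11 ± 1.03 to 9.16 ± 1.77 CPM (log2 fold change 1.56, SE 0.22, edgeR adjusted p = 0.00382). The danger signal score was 6.49 ± 0.0778 and 6.74 ± 0.110 (exact permutation p = 0.00794, adjusted 0.045), with a median log2 fold change of 0.10, a mean of 0.31 and a camera adjusted p of 0.0569, or 0.348 with an estimated correlation. Without Nt5e the difference went from 0.251 to 0.169 and did not pass (exact permutation p = 0.0714, adjusted 0.221), a test also added after the data were seen. Neither score passed without any 1 tumour other than SLR14 4 (adjusted exact permutation p 0.0540 to 0.0926) or with a median over genes (adjusted 0.528 and 0.225). With the preset correlation camera called the necroptosis list higher with DESeq2 size factors and without PBS 2 or SLR14 2, 3, 4 or 5 (adjusted p 0.0347 to 0.0474). It called the danger signal list higher without PBS 2 (0.0347) or SLR14 5 (0.00326) and with the replicate block (0.0169). Of 20 apoptosis genes 0 passed in edgeR, 3 had an unadjusted p under 0.05 and 1 passed in DESeq2, and 1 rose when adjusted over the list alone. Of 11 pyroptosis and inflammasome genes 0 passed in edgeR or DESeq2 and 1 had an unadjusted p under 0.05, and likewise of 14 unfolded protein response genes. Scores of these 3 lists did not pass (exact permutation p = 0.0635, 0.540 and 0.802), and the pyroptosis median of -0.01 and mean of 0.07 differed in sign.

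Proliferation and metabolism genes showed no single call. Of 30 cell cycle genes 0 passed in edgeR or DESeq2 and 3 had an unadjusted p under 0.05, with Mki67 at 331 ± 120 and 364 ± 64.0 CPM (SD, n = 5; edgeR adjusted p = 0.832). Of 20 glycolysis and hypoxia genes 0 passed in edgeR, DESeq2 or limma voom and 0 had an unadjusted p under 0.05. Of 22 oxidative phosphorylation genes 0 passed in edgeR or DESeq2 and 2 had an unadjusted p under 0.05, although all 22 had negative fold changes with a median of -0.12. Camera called this list lower (adjusted p = 0.00498), with adjusted p = 0.614 with an estimated correlation and 0.264 without PBS 5. Leaving out that tumour moved the median on voom values from -0.11 to -0.03, and its score of 7.26 lay above the 6.66 to 6.78 of the other PBS tumours. Adjusted over the list alone, 0 genes of these 3 lists passed. Their scores did not pass (exact permutation p = 0.690, 0.532 and 0.230).

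Of 15 renal epithelial and tumour genes 1 fell, 0 rose and 14 did not pass, and 2 fell when adjusted over the list alone. The gene was Epcam, an epithelial adhesion molecule also present on some dendritic cells, which went from 3.45 ± 1.62 to 0.617 ± 0.502 CPM (SD, n = 5; log2 fold change -2.42, SE 0.49, edgeR adjusted p = 0.0324) and lost its call without any 1 tumour other than PBS 2, PBS 5 or SLR14 5 (adjusted p 0.0547 to 0.0936). The renal epithelial score did not pass (exact permutation p = 0.175). Among genes of tissue that could be cut out with a tumour, 0 of 3 skin, 0 of 4 adipocyte, 0 of 14 skeletal muscle and 0 of 6 erythroid genes passed in edgeR, DESeq2 or limma voom, with 0, 1, 0 and 2 at an unadjusted p under 0.05. Adjusted over the list alone, 1 adipocyte gene rose and 0 genes of the other 3 lists passed. Skeletal muscle scores were 2.73 ± 0.940 and 2.52 ± 1.29 (exact permutation p = 0.778). The erythroid score was 2.95 ± 0.492 in PBS and 2.49 ± 0.693 in SLR14 tumours (exact permutation p = 0.246), and camera called the list lower (adjusted p = 0.00663), with adjusted p = 0.496 with an estimated correlation and 0.0680 without SLR14 3. Of 19 immediate early and stress genes 0 passed in edgeR, 4 had an unadjusted p under 0.05, 1 passed in DESeq2 and 2 rose when adjusted over the list alone. Of 7 mitochondrially encoded genes 0 passed in edgeR or DESeq2 and 1 had an unadjusted p under 0.05. Camera called both of these lists higher (adjusted p = 0.0110 and 0.0288, or adjusted p = 0.601 for each with an estimated correlation). The first lost its call without PBS 3, PBS 5 or SLR14 2 (adjusted p up to 0.132), the other without PBS 3, PBS 5, SLR14 1 or SLR14 2 (up to 0.392), and neither score passed (exact permutation p = 0.302 and 0.317).

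Over all 34 lists with at least 5 tested genes, camera called 9 higher and 6 lower with the preset correlation and 0 with an estimated one, where 5 had an unadjusted p under 0.05. Camera also called macrophage genes higher without PBS 3 or SLR14 3 (adjusted p = 0.0489 and 0.0215), pan-endothelial genes without PBS 3 (0.0489), cytokine and NF-kB genes without SLR14 5 (0.0299), and glycolysis genes without PBS 4 or SLR14 1, 3 or 5 and with the replicate block (0.00251 to 0.0493). Skeletal muscle genes were called higher without SLR14 2 (0.0351). Fry called 4 lists, the interferon-stimulated, class I, neutrophil and necroptosis lists. The score test called 6, these 4 and the RIG-I-like receptor and danger signal lists. It called 0 without PBS 1, 2, 3, 4 or 5 or SLR14 1, 2, 3 or 5, with adjusted p up to 0.0694 for the interferon-stimulated and necroptosis lists, 0.0926 for the neutrophil and danger signal lists, 0.111 for class I and 0.135 for the RIG-I-like receptor list. Without SLR14 4 it called 6, with erythroid genes (adjusted p = 0.0463) in place of the RIG-I-like receptor list. Of the 10 relative scores, each a list set against a list of cell type markers, 0 passed and 2 had an unadjusted exact permutation p under 0.05. Besides neutrophil against macrophage genes, this was cytotoxic effectors, a list of 4 tested genes, against T cell genes, -1.14 ± 0.138 in PBS and -0.61 ± 0.340 in SLR14 tumours (exact permutation p = 0.0397, adjusted 0.179). The score of pericyte against pan-endothelial genes was -0.09 ± 0.176 and -0.30 ± 0.116 (exact permutation p = 0.0635, adjusted 0.179), and the other 7 pairs had exact permutation p of 0.0714 to 0.683. Without SLR14 5, 3 of the 10 relative scores passed.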

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

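Of the tests below, the one on erythroid genes was chosen after the result was seen. A tumour was singled out where its gap to the nearest other tumour of its group took a larger share of the group's range than Dixon's 95% critical value. This held for 33 of 368 groups of values tested, where chance gives about 18, and values of related genes are not independent. PBS 5 accounted for 11 of the 33 and PBS 4 for 8.

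PBS 5 had the highest oxidative phosphorylation score (7.26, other PBS tumours 6.66 to 6.78) and erythroid score (3.83, others 2.69 to 2.77), and the lowest RIG-I-like receptor score (5.45, others 5.68 to 5.72). Its CPM was highest for Hbb-bs (110, others 22.8 to 34.6) and Hba-a1 (36.7, others 12.3 to 16.3). It was lowest for Plin4 (100.1, others 163 to 180.0), Klf2 (38.6, others 53.0 to 58.7), Apln (20.6, others 37.7 to 45.3), Bcl2 (71.8, others 87.6 to 91.3) and Pax2 (18.4, others 33.6 to 42.1).

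PBS 4 had the highest CPM of H2-Eb1 (199, others 93.8 to 108), H2-Ab1 (144, others 71.6 to 85.3), Adam23 (9.46, others 4.06 to 4.81) and Cd8a (0.599, others 0.105 to 0.190), and the lowest of Ccl24 (1.17, others 1.88 to 2.17) and Cd79a (0.629, others 1.47 to 1.82). Its class II score relative to macrophage genes was -0.0829 (others -0.93 to -0.69) and its cytotoxic score relative to T cell genes -1.38 (others -1.12 to -1.03). PBS 3 had a neutrophil score relative to macrophage genes of -4.49 (others -4.15 to -4.07). PBS 2 was highest for Gzmb (0.476 CPM, others 0.113 to 0.139) and Timd4 (1.78 CPM, others 0.415 to 0.627).

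SLR14 2 had no count of Myh4, a muscle myosin (0 CPM, others 48.1 to 86.5), and the lowest CPM of Col1a1 (254, others 565 to 758) and Havcr2 (4.94, others 7.59 to 8.87). SLR14 3 was lowest for Ly6c2 (0.787 CPM, others 4.82 to 5.74), Cd244a (0.609 CPM, others 1.07 to 1.25) and Vcam1 (19.2 CPM, others 27.0 to 29.5), and for the checkpoint score (2.80, others 3.04 to 3.12). SLR14 5 was lowest for Slfn1 (3.92 CPM, others 7.98 to 9.62) and Hspa5 (1221 CPM, others 1631 to 1716) and highest for Fabp4 (6.18 CPM, others 3.02 to 3.67) and Plvap (99.5 CPM, others 68.1 to 73.0).

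Neutrophil genes were higher in SLR14 tumours, with a median log2 fold change of 1.13 over 13 genes, of which 5 passed and 8 did not. Camera called the list with its preset correlation but not with an estimated one (adjusted p = 0.161). More blood in the pieces would bring red cell transcripts along. The median of 6 erythroid genes was -0.54 (95% bootstrap interval over genes -0.91 to 0.03), below the rise of 1 that this explanation was taken to need. These genes move together (estimated inter-gene correlation 0.74), and the interval holds no spread between tumours. Among SLR14 tumours, SLR14 2 and SLR14 4 had the highest neutrophil scores (3.21 and 2.86) and the highest erythroid scores (2.66 and 3.60). A share of blood in single tumours is therefore not excluded. Mean sequencing depth did not differ between the groups (exact permutation p = 0.881). With library size in the model, 5 of 5 called genes kept their direction and an unadjusted p under 0.05 (edgeR, largest p 0.000206). That fit cannot decide whether depth played a part. Mean depth barely differed between the groups, so the added term could hardly remove a group difference. The genes were also chosen for passing in the same data. It also stays open whether the genes mark more neutrophils or activation of other cells. Lcn2 and Acod1 may also come from epithelium and macrophages. That the treatment, the difference the design names, raised neutrophil transcripts remains a hypothesis; the neutrophil list was fixed before the data were examined, and SLR14 is not separated from its lipid carrier.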

How the results depend on the processing

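All alternatives but the joint removal of PBS 5 and SLR14 2, the scores without Zbp1, Nt5e or Bst2 and DESeq2 on the genes edgeR tested were chosen before the data were examined. Of 153 genes, DESeq2 size factors shared 153 calls, upper-quartile factors 129, limma voom 136, the authors' normalized values 141, no low-count filter 151, a CPM filter 125 (of 132 tested) and library size as a covariate 133, with totals of 128 to 159 and no shared call of opposite sign. DESeq2 called 407 (251 higher, 156 lower) of 18584 tested, 400 (246 higher, 154 lower) on the genes edgeR tested, and limma voom with quality weights 349 (205 higher, 144 lower); these move the share of higher calls from 69.9% to 61.7%, 61.5% and 58.7%. The weight of PBS 5 was 0.136. Leaving out 1 tumour gave 69 to 194 genes, 44 to 123 higher and 25 to 71 lower; without PBS 5 and SLR14 2 together 74 were lower, of 215. The cause of these moves was not tested, beyond fewer samples in the fits that left out tumours.

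The labels do not say whether replicate numbers pair the tumours, and the values gave no sign of it, which does not exclude pairing. Deviations of same-numbered tumours correlated at -0.203 to 0.109, and 1 of 10 tumours correlated best with its own number. With the replicate block 78 genes passed (51 higher, 27 lower) and 16 lists in camera, and 0 list scores and 0 relative scores passed, since 32 sign assignments give no p below 0.0625.

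Camera called 15 lists, 12 to 18 when 1 tumour was left out and 13 without PBS 5 and SLR14 2. It called 0 with an estimated correlation, and fry called 4. An estimated correlation above the preset 0.01 widens the null by construction. For the necroptosis and apoptosis lists, not called in the main test, the estimate was below it (-0.00783 and -0.0105). Their camera adjusted p rose all the same, from 0.0501 to 0.313 and from 0.342 to 0.496. A larger correlation within a list is therefore not the only reason for higher values in that setting. List scores passed for 6 lists, and for 0 with a median over genes, 0 without PBS 5 and SLR14 2, and 0 to 6 when 1 tumour was left out. Of the 55 losses of these 6 lists without 1 tumour, 37 kept the smallest possible p, 0.00794, so that fewer lists at it raised the adjusted p, and 18 had a larger p of their own; the cause of the other losses was not tested. Relative scores passed for 0 to 3 of 10 pairs when 1 tumour was left out, 3 without SLR14 5. Among results called in the main test or the alternative, the direction reversed in 4 cases, all in camera. The cause was not tested beyond the genes or tumours that those fits left out. Results called in neither changed sign in 27 list medians of camera, 26 list scores, 1 relative score and 16 values of named genes. The camera median of mitochondrially encoded genes, called in the main test, went from 0.372 to -0.0573 without PBS 5 and SLR14 2 (adjusted p = 0.873), while the direction of the test did not change. T cell genes under the CPM filter, which removed members such as Cd3e and Cd8a, had a median of -0.0431 (camera adjusted p = 0.750). Skeletal muscle genes had -0.744 to 0.554 when 1 tumour was left out, and 0.554 without SLR14 2 (camera adjusted p = 0.0351). Without PBS 5 and SLR14 2 they had 0.715 (camera adjusted p = 0.000942), and tip cell genes -0.172 (camera adjusted p = 0.0490). Both skeletal muscle reversals left out SLR14 2, which had the lowest muscle score of the SLR14 tumours (0.310, others 2.51 to 3.51). Of 40 named genes called, 23 were called in each of 15 alternatives and 17 lost the call in at least 1; of 99 not called, 21 gained it in at least 1. Depth limits genes under about 1 CPM most: SLR14 2, with 17931895 counts, gives the fewest counts per gene.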

Other observations

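Of the tests below, those on dendritic cell genes and on the score of resident macrophage genes were chosen, and the reading of the interleukin-4 test was revised, after the result was seen; the lists for fibroblasts, the interleukin-4 response, resident macrophages and the falling group were written after the falling genes were known. Several genes outside the lists shared the fall of Cd209a, and they are named after their values were seen. Cd209b (log2 fold change -4.84, SE 0.48, edgeR adjusted p = 0.000406) and Cd209d (-4.56, SE 0.64, edgeR adjusted p = 0.00369), neighbours in the same lectin family, fell with it, and the SLR14 levels of 0.0618 and 0.0621 CPM rest on few counts. Reads are shared between these copies to an unknown extent. Mgl2, the lectin CD301b, went from 49.9 ± 10.9 to 18.6 ± 4.69 CPM (SD, n = 5; edgeR adjusted p = 0.00254), and Irf4, a transcription factor of type 2 dendritic cells and of alternative macrophages, fell by 1.43 on the log2 scale (SE 0.29, edgeR adjusted p = 0.0330). Dpp4 fell by 2.32 on the log2 scale (SE 0.43, edgeR adjusted p = 0.0235). Irf4 lost its call without any 1 tumour other than PBS 5 or SLR14 2 (adjusted p 0.0602 to 0.109) and Dpp4 without PBS 1, SLR14 1 or SLR14 3 (0.0589 to 0.0714), while Cd209b, Cd209d and Mgl2 kept theirs in all 10 such fits.

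Resident macrophage genes had negative fold changes in 10 of 11 genes, with a median of -0.80. The smallest edgeR adjusted p among them was that of Selenop, which was at 1486 CPM in PBS and 893 CPM in SLR14 tumours (means, edgeR adjusted p = 0.0726), and F13a1 at 184 and 91.1 CPM (edgeR adjusted p = 0.405). The score of this list was 5.07 in PBS and 4.37 in SLR14 tumours (exact permutation p = 0.0476, n = 5 each). In the same tumours the general macrophage and monocyte list had a median of 0.07.

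The 9 genes of the falling group, Asgr2, Cd209a, Cd209b, Cd209d, Ear2, Alox15, Ccl17, Ccl24 and Mgl2, had a median log2 fold change of -3.57. A loss of dendritic cells in total, as the whole cause, would lower dendritic cell genes alike. The group's interval over genes, -4.56 to -1.92, cannot say by how much, because its genes were chosen for their falls. Mgl2, its member with the highest level (49.9 CPM in PBS tumours), had a log2 fold change of -1.43, outside that interval. The median of 11 dendritic cell genes, Cd209a among them and Bst2 left out, was -0.70 (95% bootstrap interval over genes -0.98 to 0.06). That interval lay only narrowly above the -1 set for this explanation and holds no spread between tumours. Members also went both ways, 3 up and 8 down, so the test cannot decide the question. That test was respecified after a first version, which also left out Cd209a, had given a median of -0.50 (interval -0.93 to 0.12); with both genes kept it was also -0.50 (interval -0.96 to 0.16). A loss of dendritic cells is not excluded. For less skin and connective tissue around the tumour, the median of 10 universal fibroblast genes was -0.52 (interval -0.90 to 0.11). That interval lay above the -1.5 set for this explanation. The test cannot decide the question, because members went both ways, 4 up and 6 down. Dpp4, the 1 called member, fell by 2.32, while Gsn and Igfbp6, at 302 and 136 CPM in PBS tumours, had 0.11 and 0.18. A weaker interleukin-4 and interleukin-13 response, in which Ccl17, Ccl24, Alox15 and Mgl2 are known targets, cannot be told apart from the rest. The 11 other response genes had a median of 0.0820 (interval -0.30 to 0.77), which met the bound set in advance against this explanation. That bound was judged wrong after this interval was seen. It asked a response to move all its genes alike, and the members went both ways, from -1.16 for Pdcd1lg2 to 1.51 for Rnase2a, in a list that left out the 4 targets in the pattern itself. A candidate explanation that stays open is the loss of a myeloid subset that carries these lectins, or its change of state, which bulk RNA does not separate.

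The 153 genes were set against other splits of the 10 tumours into groups of 5. Of 100 splits drawn from the 126 possible, 1 gave as many genes, the real one, and the highest of the others gave 1 gene. The real split was always among those drawn, so 1 of 100 was the lowest share possible. The other splits mixed SLR14 and PBS tumours in both groups. Any treatment difference then adds to the spread within groups, which favours low counts. Chance is limited for the gene count but not excluded. For the 15 lists called by camera with its preset correlation, 5 of 100 splits gave as many, and the highest other gave 18, so chance cannot be excluded for that count. This count does not test any single list.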
